A study of Mus musculus with 316 samples.

How the data were processed

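The data are raw read counts per gene and cell, deposited by the authors as 1 table of 11463 genes by 316 cells. That the values are counts follows from the deposited table itself: whole numbers from 0, with totals that differ widely between cells. Per the submitters' processing notes, Bowtie 0.12.2 and the genome builds mm10 and GRCm38 were used; the role of each, the counting tool, the annotation, the use of strand and any filter on genes or cells are not given in the sources used here. Every listed gene has a read in at least 5 cells, so genes seen in fewer cells are missing from the table, and a level of 0 in a group is that of a gene seen elsewhere. Gene symbols were matched to GENCODE M21 (GRCm38), from which coordinates and overlapping genes were taken; 11224 of the 11463 symbols matched. No 2 cells held identical values.

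Per the labels' protocols, hippocampi of 4 mice were pooled per sample, dissociated with a commercial enzymatic kit, and endothelial cells were isolated by fluorescence-activated sorting. Each sequenced sample is 1 cell, and cells are not replicates. The replicate is the pool, numbered 1 and 2 within each age, and each number goes with a single barcode prefix. All 316 cells entered the main results, with no filter on cells and no doublet caller; 13 cells had fewer than 2000 reads. Mitochondrial genes took 2.81% and Rn18s-rs5, a ribosomal RNA gene, 3.10% of reads. Genes detected per cell averaged 1902 ± 100.0 in pos and 1497 ± 34.4 in neg pools (SD, n = 4; exact permutation p = 0.0286). With every cell thinned to 183530 reads, which kept 284 cells (142 pos and 142 neg), they averaged 1832 ± 137 and 1514 ± 144 (exact permutation p = 0.0571).

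Counts were summed over the cells of each pool and gate, giving 8 sums, or over both gates of a pool for the comparison of ages, giving 4. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood test) with 1 coefficient per age and gate, and called at a Benjamini-Hochberg adjusted p under 0.05. CPM values were computed here from those deposited counts and the effective sizes of the sums. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 29 lists, and again with an estimated correlation. The lists cover vessel segments, other brain and blood cell types and endothelial functions; the erythrocyte list had 0 members in the table and the neuron list 1, Stmn2, which the arterial list also holds. Shares of cells with a Vcam1 read and list scores per cell (mean log2(CPM + 1) of the list) were averaged per pool and compared by two-sided exact permutation over pools. Cells with at least 1000 genes were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (1500 variable genes, 10 components, 15 neighbours, resolution 0.5), and clusters were named from the marker lists.

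The tests, the lists, the other settings to be tried and the rule for naming genes were fixed before the data were examined. For the 2 main contrasts the rule takes up to 12 higher and 12 lower genes with the largest fold changes among those past the test, with a mean of at least 32 CPM and the same sign in every pool, filled to 6 by smallest p and then said to be short of the test. For the other contrasts it takes 5, filled to 3. Vcam1 and up to 4 members of each list described are named besides, and predicted genes without an established symbol are passed over. A few genes that the rule names are not reported here. Floors are 3 reads per sum, intervals are exact 95% binomial, and both cover counting error only.

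Both gates of a pool come from the same mice, by the labels, so the pool pairs them, and edgeR was also fitted with the pool as a block. Correlations of the deviations of same-pool sums from their group means were small, 0.0132 to 0.0193. Numbers 1 and 2 pair no mice between ages, but each goes with 1 barcode prefix in both ages; 0 genes differed between them in edgeR (266 at an unadjusted p under 0.05), and 2 lists did in limma's camera when the 8 sums were split by number. Other alternatives were other size factors (RLE), no low-count filter, DESeq2 1.42.0, limma-trend on mean CPM per cell, thinned cells, cells with at least 1000 genes, cells that do not resemble other types, and leaving out each pool.

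The tests were run on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold, all with a mean of at least 32 CPM. The sums were drawn independently, with no pool effect, so the simulation cannot decide between the fits with and without the block. Its recovery does not carry over to genes at lower levels. For the contrast of gates (10446 genes) edgeR recovered 31 and 80 of them with 10 wrong calls, edgeR with the block 29 and 82 with 15 wrong calls, and DESeq2 54 and 94 with 350 wrong calls. For the contrast of ages (10426 genes) edgeR made 3 wrong calls, and DESeq2 recovered 50 and 97 with 114 wrong calls.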

Results

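Gene expression was measured in 316 single brain endothelial cells from the hippocampi of male C57BL/6 mice aged 3 months (young) or 19 months (aged). Brain endothelial cells line the vessels and form the blood-brain barrier, and they differ between arteries, capillaries and veins. Hippocampi of 4 mice were pooled before dissociation and sorting, with 2 pools per age. From each pool, cells were taken in a gate labelled pos and a gate labelled neg. The labels do not name the marker of the gate; the series title names VCAM1, an endothelial adhesion molecule that binds leukocytes. The young pools gave 46 and 47 pos cells and 46 and 48 neg cells, and the aged pools gave 22 and 40 pos cells and 26 and 41 neg cells. A cell had a median of 502800 reads and 1740.5 detected genes. Reads summed over the cells of a pool and gate ranged from 8953162 to 31366989. Of the cells, 10 of 155 in the pos gate and 26 of 161 in the neg gate had fewer than 1000 detected genes.

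The first question was how the gates differ in Vcam1 itself. Vcam1 (ENSMUSG00000027962.14, minus strand of chromosome 3 at 116109949 to 116129688 in GRCm38) had at least 1 read in 59.3% ± 14.1 of pos cells and in 5.28% ± 6.92 of neg cells (SD, n = 4 pools). The share was higher in the pos gate of 4 of 4 pools, by a mean of 54.1 points (two-sided exact permutation test over pools, p = 0.0286, the smallest that 4 against 4 allows). If the gate was set on VCAM1, this difference describes the sort and is no separate finding. When the gates were exchanged only within pools, the exact p was 0.125, the smallest that 4 pools allow. In the summed reads Vcam1 stood at 1526 ± 943 CPM in pos and 8.49 ± 13.2 CPM in neg pools (SD, n = 4). A single cell held 84.8% of the 847 Vcam1 reads of the neg gate, and without young pool 1 the neg mean was 2.03 CPM.

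By age, Vcam1 was read in 19 of 46 and 27 of 47 young pos cells (41.3% and 57.4%) and in 14 of 22 and 30 of 40 aged pos cells (63.6% and 75%). In the neg gate it was read in 3 of 46 and 7 of 48 young cells (6.52% and 14.6%). None of the aged neg cells had a read, 0 of 26 and 0 of 41. Over both aged pools, 0 of 67 cells allows a share of up to 4.48% (3 counts), with an exact Clopper-Pearson upper bound of 5.36%. An exact permutation of 2 pools against 2 cannot give a two-sided p under 0.333, so none is given for these shares. Reads carry no molecular identifiers here, so these intervals and limits cover counting error only.

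**Figure D1:**
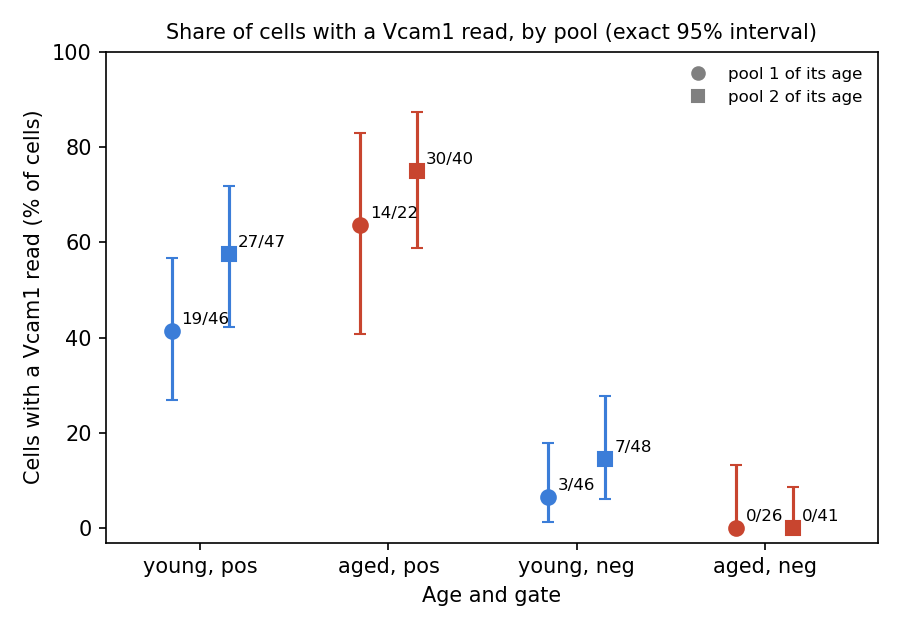
Share of cells with at least 1 Vcam1 read (percent of cells, vertical axis) for each pool, grouped by age and gate, with exact 95% binomial intervals; the numbers beside the points are cells with a read over all cells. The 4 pos pools lie between 41.3% and 75%, and the 4 neg pools between 0% and 14.6%.

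The gates also differed in vessel segment. Pos cells had higher levels of arterial and venous marker genes, and neg cells had higher levels of capillary markers. The arterial list (20 genes, among them Gkn3, Bmx and Sema3g) averaged 3.16 ± 0.60 on the log2(CPM + 1) scale in pos and 1.31 ± 0.17 in neg pools (SD, n = 4). The venous list (18 genes, among them Nr2f2, Vwf and Lrg1) averaged 2.94 ± 0.38 in pos and 1.11 ± 0.23 in neg pools. The capillary list (17 genes, among them Mfsd2a, Car4 and Tfrc) averaged 3.33 ± 0.29 in pos and 5.90 ± 0.21 in neg pools. Each of these differences, of 1.84, 1.83 and -2.57, had the same sign in 4 of 4 pools (two-sided exact permutation p = 0.0286 each, Benjamini-Hochberg adjusted p = 0.0381 over 4 tests). Within pools the exact p was 0.125 for each. The pan-endothelial list, with Pecam1, Cldn5 and Cdh5, averaged 7.93 ± 0.29 in pos and 8.0 ± 0.36 in neg pools, a difference of -0.07 that did not pass (exact permutation p = 0.886). This difference depends on the cells and pools used: it was -0.40 with thinned cells (p = 0.314), -0.48 with at least 1000 genes per cell (p = 0.114) and 0.07 without aged pool 2.

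**Figure D2:**
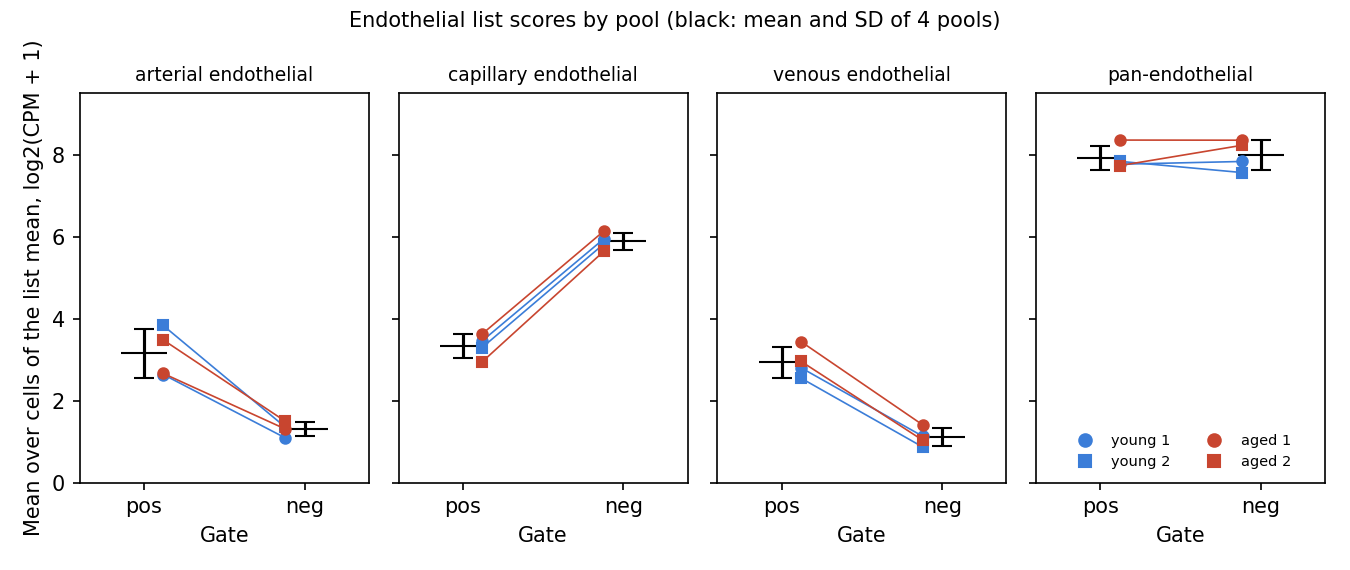
Mean over cells of each list's mean log2(CPM + 1) (vertical axis) in the pos and neg gates, with a line per pool and black marks for the mean and SD of 4 pools. The capillary score lies between 2.95 and 3.63 in pos and between 5.65 and 6.15 in neg pools, and the pan-endothelial score overlaps between the gates.

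Gene by gene, the pos gate was marked by genes of veins and arteries and by adhesion and inflammatory genes, which here overlap with the venous ones. Among the venous genes, Lrg1, a secreted glycoprotein, stood at 560 ± 206 CPM in pos and 22.4 ± 28.8 CPM in neg pools (SD, n = 4; 9.63 CPM in neg without aged pool 2), with 81.2% of its neg reads in a single cell. Ch25h, which makes 25-hydroxycholesterol, stood at 287 ± 234 CPM in pos pools and had 1 read in the whole neg gate. Of arterial genes, Gkn3 stood at 641 ± 314 and 38.0 ± 17 CPM, and the secreted factor Cytl1 at 592 ± 143 and 0.455 ± 0.909 CPM. Icam1, an adhesion molecule for leukocytes, stood at 197 ± 95.4 and 1.87 ± 3.45 CPM, with 95.3% of its neg reads in a single cell (0.147 CPM in neg without young pool 1). Ptgs2, the inducible cyclooxygenase, stood at 152 ± 172 CPM in pos pools and had 3 reads in the neg gate, with 37.7% of its pos reads in a single cell. Without aged pool 2 the pos means of Ch25h and Ptgs2 were 174 and 71.4 CPM.

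In 10571 tested genes, edgeR called 40 between the gates at an adjusted p under 0.05, of which 27 were higher and 13 lower in pos cells. At an unadjusted p under 0.05 there were 1181 genes, where 528.55 are expected by chance. Of the called genes, 39 differed in the same direction in 4 of 4 pools; the exception was Prune2. Vcam1 was among the called genes (edgeR adjusted p = 0.00626), with Gkn3 (log2 fold change 4.07 ± 0.35, SE) and Lrg1 (7.77 ± 0.71). The orphan receptor gene Gpr182 stood at 80.2 ± 37.0 CPM in pos pools and had no read in neg cells, 436-fold against a floor of 3 reads per sum. That floor counts reads and is no bound in transcripts: Gpr182 was read in 21 of 155 pos and 0 of 161 neg cells. Gpm6a, a membrane glycoprotein, and Sdc1, a heparan sulfate proteoglycan, stood at 84.9 ± 36.6 and 100.2 ± 35.7 CPM in pos pools and had 1 and 2 reads in the neg gate. Cmip stood at 190.0 ± 81.2 and 4.48 ± 6.42 CPM, and the calcium pump gene Atp2a3 at 183 ± 61.4 and 23.4 ± 27.3 CPM. H2-Q6, a class I histocompatibility gene with near-identical copies and therefore uncertain, stood at 296 ± 206 and 32 ± 37.5 CPM. The neg levels of these 3 genes rest on the aged pools: without aged pool 1 they were 1.35 CPM for Cmip and 13.7 CPM for Atp2a3, and without aged pool 2 18.3 CPM for H2-Q6. With the pool as a block, edgeR called 0 of these genes (699 at an unadjusted p under 0.05). The 40 genes then had a median absolute log2 fold change of 2.54 (median SE 0.30), against 2.53 (0.31) without it, and all 40 had an unadjusted p under 0.05. Why the calls ended was not tested. DESeq2 without the block called 1478. Leaving out young pool 1, young pool 2, aged pool 1 or aged pool 2 left 2, 1, 0 and 0 calls (Vcam1 was called without either young pool), and leaving out 69 cells that scored above pan-endothelial on any list of another cell type left 10.

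Of the 13 genes lower in pos cells, 7 belong to the capillary list and 3 to the barrier transporter list, with Mfsd2a and Slc16a1 in both. Cxcl12, a chemokine made by capillary endothelium, stood at 419 ± 186 CPM in pos and 4106 ± 1158 CPM in neg pools and fell by 3.27 on the log2 scale. Mfsd2a, the lipid transporter that carries docosahexaenoic acid into the brain, fell by 3.03 (95.2 ± 43.1 against 766 ± 171 CPM). Car4, a carbonic anhydrase of the capillary surface, fell by 1.92 (641 ± 186 against 2377 ± 443 CPM), and Kdr, the main VEGF receptor, by 2.15 (124 ± 33.8 against 555 ± 113 CPM). The lactate transporter gene Slc16a1 had a log2 fold change of -2.05, and Slco1c1, which carries thyroid hormone, of -1.78. Hmcn1, an extracellular matrix gene, and Ddc, aromatic amino acid decarboxylase, had log2 fold changes of -2.53 and -2.46, followed by Spock2 (-1.70), the IGF1 receptor gene Igf1r (-1.66) and Sparcl1 (-1.31). Bsg, an abundant barrier glycoprotein, stood at 11332 ± 655 CPM in pos and 22377 ± 948 CPM in neg pools (-0.98). These 12 genes were lower in the pos gate of 4 of 4 pools, and the edgeR adjusted p of the 24 genes with the largest differences ran from 0.00626 to 0.0440. Gene neighbours on the opposite strand overlap Vcam1, Ch25h, Gpr182, Icam1, Hmcn1, Ddc and Sparcl1, and same-strand genes overlap Gpm6a, Cmip, Slc16a1 and Spock2. The sources used here do not say whether counting used the strand, so reads of these loci are uncertain to that extent.

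**Figure D3:**
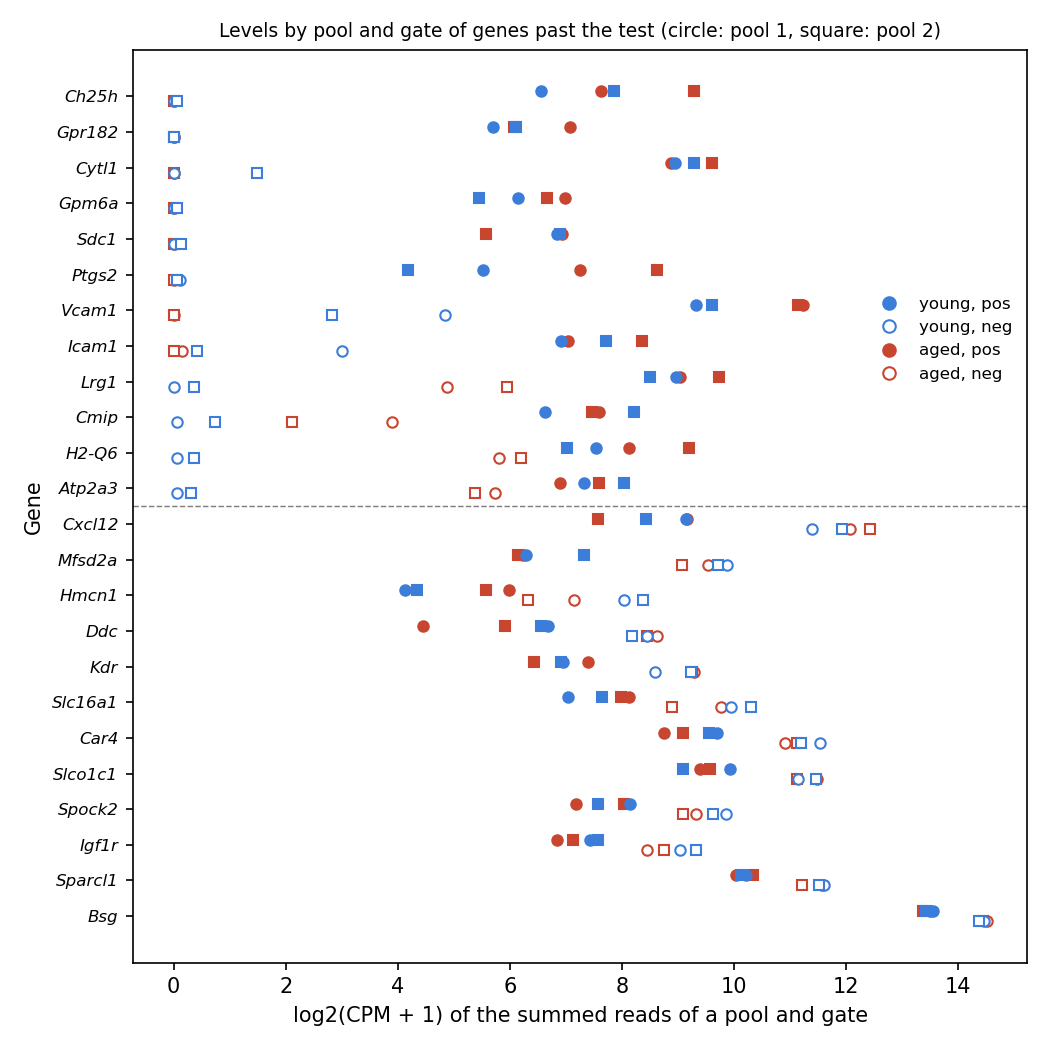
Level of each of the 12 higher and 12 lower genes with the largest differences between gates, as log2(CPM + 1) of the summed reads of a pool and gate (horizontal axis); filled symbols are pos, open symbols neg, circles pool 1 and squares pool 2 of each age. Filled and open symbols separate for the genes above the dashed line, which are higher in pos, and for those under it, which are lower.

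Of 29 gene lists tested between the gates with limma's camera at a preset correlation, 12 passed, 8 higher and 4 lower in pos cells. The capillary, venous and adhesion lists also passed with an estimated correlation, and no other did. In the capillary list, 7 of 17 tested members fell over all genes and 16 when adjusted over the list alone (camera adjusted p = 1.39e-15; adjusted p = 0.0239 with an estimated correlation). In the venous list, 4 of 18 members rose, among them Ch25h, Lrg1 and Icam1, and 13 rose when adjusted over the list alone (camera adjusted p = 1.64e-11; adjusted p = 0.0407 with an estimated correlation). The adhesion and inflammatory activation list had 4 of 24 members higher, Vcam1, Lrg1, Ptgs2 and Icam1, and 10 when adjusted over the list alone (camera adjusted p = 3.27e-09; adjusted p = 0.0407 with an estimated correlation). Without Vcam1, which may be the gate's own marker, its other 23 members still passed (camera adjusted p = 6.45e-08, and 0.0407 with an estimated correlation), in a test added after the values were seen. The adhesion list overlaps with venous identity here, and whether it differs between the gates apart from vessel segment was not tested. Lrg1 and Icam1 are on the venous list too. Lrg1, Ptgs2 and Icam1 were all among the 10 genes with the largest fold in the venous-like cells clustered below. Vcam1 went the other way: among pos cells it was read in 76.9% of arterial-like and 48.4% of venous-like cells. The immediate early and dissociation stress list, which responds to handling, also scored higher per cell in the pos gate of 4 of 4 pools (3.02 and 3.46 against 2.12 and 2.26 in young, 3.50 and 3.48 against 2.97 and 3.06 in aged pools, mean log2(CPM + 1)). On summed reads the median of its members was higher in 2 of 4 pools, and it did not pass (camera adjusted p = 0.305).

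In the arterial list, Gkn3 and Cytl1 rose among 20 members, and 13 rose when adjusted over the list alone (camera adjusted p = 7.87e-10; adjusted p = 0.0980 with an estimated correlation). Of 29 blood-brain barrier transporter genes, Mfsd2a, Slco1c1 and Slc16a1 fell, and 16 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.49e-08; adjusted p = 0.0980 with an estimated correlation). Of 21 class I antigen presentation genes, 3 rose, 6 when adjusted over the list alone (camera adjusted p = 0.00648; adjusted p = 0.196 with an estimated correlation). They were H2-Q6, H2-K1 (2579 ± 657 against 1233 ± 194 CPM) and H2-D1 (5297 ± 959 against 3214 ± 708 CPM; SD, n = 4), which share sequence with other class I genes. Of 18 pan-endothelial genes, Itm2a and Kdr fell, 6 when adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.246 with an estimated correlation). Itm2a stood at 5945 ± 793 CPM in pos and 11553 ± 1625 CPM in neg pools.

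Cytoplasmic ribosomal protein genes leaned to the pos gate as a group: 75 of 79 had a positive log2 fold change, while 0 passed singly (camera adjusted p = 0.00392; adjusted p = 0.272 with an estimated correlation). Rpl4 stood at 1085 ± 145 and 761 ± 204 CPM (SD, n = 4). The Notch list, a pathway of arterial fate, was higher with 0 of 14 members past the test over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0297; adjusted p = 0.204 with an estimated correlation). Its members Jag1 and Notch1 stood at 475 ± 160 and 220.4 ± 30.6 CPM in pos and at 175 ± 26.4 and 145 ± 47.8 CPM in neg pools. The Wnt and barrier-inducing list was lower, with 0 of 22 members past the test over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0297; adjusted p = 0.272 with an estimated correlation). In that list Ctnnb1, encoding beta-catenin, stood at 615 ± 200 CPM in pos and 1044 ± 207 CPM in neg pools, and Sox17 at 1170 ± 315 and 700.5 ± 89.9 CPM. Sox18, Lef1, Mfng and Hey1 had log2 fold changes of 0.32, -0.15, 0.13 and 0.55, none past the test.

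Markers of some other cell types moved with the gate too. The fibroblast list was higher in pos cells, on 2 tested members, of which Apod, a lipocalin, rose (487 ± 225 against 147 ± 33.8 CPM; SD, n = 4; limma camera adjusted p = 0.00603, adjusted p = 0.159 with an estimated correlation). The smooth muscle list was higher on 2 tested members, 0 past the test over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0297; adjusted p = 0.210 with an estimated correlation). These were Mylk, at 91.0 ± 51.0 and 9.74 ± 11.2 CPM, and Myl9, at 15.7 ± 9.55 and 11.1 ± 22.2 CPM; in neg they stood at 5.10 CPM without aged pool 2 (Mylk) and 0.0289 CPM without aged pool 1 (Myl9). On lists of at least 3 genes, 5 cells scored higher for another cell type than for the pan-endothelial list: 3 and 1 in the young pos gates and 1 in an aged neg gate. The other 17 lists did not pass (camera adjusted p from 0.101 to 0.996): neuron, mitochondrially encoded, nuclear oxidative phosphorylation, immediate early and dissociation stress, oligodendrocyte, haemostasis, junctions, unfolded protein response, pericyte, extracellular matrix, astrocyte, cell cycle, TGF-beta and BMP signalling, microglia, senescence, blood leukocyte and interferon. For the interferon and leukocyte lists, which leaned lower in the test, the median and mean differences of their members were positive.

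Within young pools 7 genes passed the same contrast, all higher in pos cells. Lrg1 stood at 432 ± 97.4 CPM in pos and 0.144 ± 0.203 CPM in neg pools, Gkn3 at 878 ± 132 and 24.8 ± 6.67 CPM, and Atp2a3 at 211 ± 74.1 and 0.139 ± 0.142 CPM (SD, n = 2). Prune2 stood at 216 ± 31.3 CPM in pos pools and had 1 read in young neg cells, 0.0239 ± 0.0338 CPM. H2-Q6 stood at 157 ± 39.1 and 0.163 ± 0.176 CPM. The edgeR adjusted p of these 5 genes ran from 0.0354 to 0.0456; 641 genes had an unadjusted p under 0.05, DESeq2 called 723, and with the pool as a block edgeR called 0. Vcam1 stood at 713 ± 98.0 against 17 ± 15.4 CPM and fell short (log2 fold change 5.39, edgeR adjusted p = 0.107), as did Car4 (-1.75), Hmcn1 (-4.05) and Mfsd2a (-2.91), which were lower in 2 of 2 pools. In limma's camera 10 lists passed, 7 higher and 3 lower; the capillary list alone held with an estimated correlation (adjusted p = 0.0268), while the venous and adhesion lists had an adjusted p = 0.0584 with an estimated correlation. For the other lists that passed, the adjusted p with an estimated correlation was 0.123 (arterial, barrier transporters), 0.149 (class I, smooth muscle, fibroblast), 0.308 (pan-endothelial) and 0.376 (immediate early and dissociation stress, higher in pos cells). With the pool as a block 9 lists passed, since the pan-endothelial list no longer did (adjusted p = 0.0364 without and 0.0773 with the block).

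Within aged pools Vcam1 stood at 2339 ± 113 CPM in pos pools and at 0 in neg pools (SD, n = 2). Against a floor of 3 reads per sum that is 9810-fold, and 7503-fold without aged pool 2. Reads carry no molecular identifiers, so this is no lower bound on the fold in transcripts. By cells, Vcam1 was read in 44 of 62 aged pos and 0 of 67 aged neg cells. Vcam1 fell just short of the test (edgeR adjusted p = 0.0508, higher in 2 of 2 pools). Ch25h, at 412 ± 303 CPM (198 and 627 in the pools) and 0, and Sat1, the polyamine acetyltransferase, at 763 ± 71.8 and 179.7 ± 0.456 CPM, were also short of it, as were Car4 (-2.09), Bsg (-1.04) and Mfsd2a (-3.15). No gene passed in edgeR, with 917 at an unadjusted p under 0.05, and DESeq2 called 1222. Without young pool 1 or young pool 2, edgeR called 1 gene, Vcam1. In limma's camera 6 lists passed and 0 held with an estimated correlation: capillary and adhesion (adjusted p = 0.0540 with an estimated correlation), venous (0.0712), arterial (0.245), barrier transporters (0.258) and ribosomal (0.427).

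Age was compared next, with both gates of a pool summed. Each sum mixes the gates in the numbers of cells taken at the sort, so its levels are not those of all hippocampal endothelial cells. Vcam1 stood at 1197 ± 44.8 CPM in aged and 393 ± 36.8 CPM in young pools (SD, n = 2; log2 fold change 1.61 ± 0.17, SE) and did not pass over all genes (edgeR adjusted p = 0.807). Other genes at higher levels in 2 of 2 aged pools, all short of the test, were the class I gene H2-Q7 (202 ± 34.8 against 50.8 ± 11.1 CPM), the vault protein gene Mvp (233 ± 12.5 against 84.0 ± 7.62 CPM), the Golgi protein gene Golgb1 (141 ± 1.72 against 36.1 ± 5.12 CPM), the transcription factor gene Bhlhe40 (422 ± 33.2 against 194 ± 16.6 CPM) and the nuclear envelope gene Sun1 (245 ± 10.6 against 78.1 ± 22.8 CPM). Plvap, a component of fenestrae that mature brain capillaries lack, had reads in 9 young cells (109 ± 86.3 CPM, with young pools at 47.7 and 169.8) and in 0 aged cells. Ube2e3 (37.8 ± 2.18 against 126 ± 8.20 CPM), Map1lc3b (489 ± 8.13 against 815 ± 43.7 CPM), Serinc3 (440 ± 153 against 1167 ± 288 CPM) and Sat1 (481 ± 36.7 against 806 ± 3.87 CPM) stood lower in aged pools. In edgeR 0 of 10634 genes passed and 503 had an unadjusted p under 0.05, against 531.7 expected from evenly spread p-values, while DESeq2 called 570. Splits that put aged pool 1 with young pool 1, or with young pool 2, gave 324 and 313 such genes in edgeR. DESeq2 called 283 and 343 in those splits. Age thus gave more small p-values than either of them, though there are too few splits for a test. On simulated counts for the comparison of ages (10426 genes), edgeR recovered 19 of 100 genes changed 4-fold and 88 of 100 changed 16-fold. These changed genes all had a mean of at least 32 CPM.

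A single list passed between the ages, the 27 tested immediate early and dissociation stress genes, which respond within minutes to handling and enzymes. It was higher in aged pools, with 22 members of positive sign and 0 past the test singly or adjusted over the list alone (limma camera adjusted p = 0.00553; adjusted p = 0.993 with an estimated correlation). Hspa8 stood at 2294 ± 383 and 1688 ± 259 CPM, Hspa1a, which has a near-identical copy, at 1480 ± 598 and 779.6 ± 459.2 CPM, Dusp1 at 1128 ± 196 and 863 ± 109 CPM, and Hspb1 at 799 ± 55.6 and 870 ± 113 CPM in aged and young pools (SD, n = 2). Leaving out young pool 1, aged pool 1 or aged pool 2 left 0 lists. The other 28 lists had a camera adjusted p from 0.190 (interferon response, higher) to 0.989. The adhesion list had an adjusted p of 0.369 in camera, with a median difference of 0.30 and a mean of -0.08.

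Within the pos gate, Vcam1 stood at 2339 ± 113 CPM in aged and 713 ± 98.0 CPM in young pools (SD, n = 2; log2 fold change 1.71, edgeR adjusted p = 1, higher in 2 of 2 pools). The Toll pathway regulator gene Tollip (280 ± 50.1 against 74.8 ± 19.2 CPM), the phosphatase gene Ppp1cb (461 ± 275 CPM, with aged pools at 655 and 266, against 134 ± 19.98 CPM) and Apod (672 ± 58.6 against 301 ± 102 CPM) were higher in aged pools, short of the test. Bin3, at 0 against 64.0 ± 27.6 CPM, Adm, the vasodilator adrenomedullin, at 0 against 35.2 ± 23.8 CPM (young pools at 52.1 and 18.4), and Clpb, at 0.0242 ± 0.0342 against 77.7 ± 12.8 CPM, were lower, also short of it. In edgeR 0 genes passed, with 360 at an unadjusted p under 0.05, and DESeq2 called 392; 0 lists passed in limma's camera, the lowest adjusted p being 0.0630 for interferon response.

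Within the neg gate, Vcam1 went the other way, with 0 CPM in aged and 17 ± 15.4 CPM in young pools (SD, n = 2; 27.9 in young pool 1 and 6.08 in young pool 2), short of the test (edgeR adjusted p = 0.196). H2-Q6 (63.8 ± 12.9 against 0.163 ± 0.176 CPM), Atp2a3 (46.7 ± 8.25 against 0.139 ± 0.142 CPM) and Prune2 (64.5 ± 48.6, with aged pools at 30.1 and 98.9, against 0.0239 ± 0.0338 CPM) stood higher in aged neg pools, while the lysosomal protease gene Ctso (53.9 ± 14.5 against 317 ± 44.4 CPM) and the splicing factor gene Aar2 (0 against 107 ± 30.9 CPM) stood lower; none passed. In edgeR 0 genes passed, with 689 at an unadjusted p under 0.05 and a smallest adjusted p of 0.173, and DESeq2 called 921. The immediate early and dissociation stress list was higher in aged neg pools (limma camera adjusted p = 0.000735; adjusted p = 0.726 with an estimated correlation). With the pool number as a block, the smooth muscle list passed besides it, on 2 members (camera adjusted p = 0.0461; without the block 0.136).

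The difference between the gates was then compared between the ages. On the log2 scale, Vcam1 had the higher pos over neg difference in aged pools, and Prune2, Atp2a3 and H2-Q6 in young pools, none past the test (edgeR adjusted p = 0.294 for Vcam1, Prune2 and Atp2a3, and 0.339 for H2-Q6). In aged pools Prune2 was not higher in pos, at 26.6 and 30.4 CPM against 30.1 and 98.9 CPM in neg. In CPM, H2-Q6 differed more in aged pools (281 and 590 in pos, 54.7 and 73.0 in neg) than in young pools (185 and 130 in pos, 0.0387 and 0.287 in neg). Ctso and Txndc11 leaned the way of Vcam1 (edgeR adjusted p = 0.339 and 0.600). In edgeR 0 of 10571 genes passed this interaction, with 560 at an unadjusted p under 0.05, and DESeq2 called 807; 0 lists passed in limma's camera.

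Clustering of the 280 cells with at least 1000 genes gave 3 clusters. Among the 10 genes with the largest fold over other cells, the listed markers were Hmcn1, Cxcl12, Rgcc and Mfsd2a in capillary-like cells (139), Fbln5, Cytl1, Gkn3 and Mgp in arterial-like cells (72), and Lrg1, Ch25h, Il1r1, Icam1 and Nr2f2 in venous-like cells (69). Several of these genes differ between the gates, so the sizes of these clusters are not compared between them. Clustered without the genes called between the gates, arterial cells were 63 pos and 7 neg, and venous cells 46 pos and 1 neg. Capillary cells then fell in clusters of 13 pos and 85 neg and of 23 pos and 42 neg cells. In the first clustering, Vcam1 was read among pos cells in 50 of 65 arterial-like cells (76.9%, exact 95% interval 64.8% to 86.5%), 31 of 64 venous-like cells (48.4%, 35.8% to 61.3%) and 7 of 16 capillary-like cells (43.8%, 19.8% to 70.1%).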

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

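All tests of explanations in this part were chosen after the result was seen. Vcam1 moved with age in opposite directions in the gates: the aged minus young change in its share of cells was 30.5 points larger in pos than in neg pools. Both aged pos pools lay above both young pos pools, and both aged neg pools lay under both young neg pools. As an edgeR interaction on counts it did not pass (adjusted p = 0.294). In a linear model of the 8 shares, added after the values were seen, p was 0.0459 (SE 10.7 points), and 0.0485 with the gates paired in pools. At a minimum of 10 CPM these were 0.0272 and 0.0530, and without young pool 1, young pool 2, aged pool 1 or aged pool 2 the unpaired p was 0.115, 0.0725, 0.147 and 0.253. The model assumes 1 spread for all groups, while both aged neg pools stand at 0, so this remains a hypothesis.

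Depth was argued against as the whole cause. With every cell thinned to 183530 reads, the pos share with a read was 30.4 points higher in aged than in young pools. Without thinning it was 19.9 points higher. The change in pos minus that in neg was 38.5 points with thinned cells and 30.5 without thinning. Thinning kept 16 of the 22 cells of aged pos pool 1. Another mix of vessel segments among aged pos cells was argued against too, since young shares per vessel class predict a change of -2.23 points where 22.4 were seen. A boundary between the gates that lay higher in aged pools would leave more Vcam1 cells in the aged neg gate, and the aged minus young share there was -10.6 points. It was -8.14 points with thinned cells and -4.26 points at a minimum of 10 CPM, so the size rests largely on cells with few reads. The exact intervals at 1 read or more, 0% to 5.36% and 5.22% to 18.7%, overlap. They count cells of both pools as independent, and overlap is no test of a difference. In the linear model of pool shares, the neg change had p = 0.234 in percent and 0.0196 after an arcsine square-root transform. At a minimum of 10 CPM that model gave 0.557 and 0.0592. A shifted boundary therefore stays open and may act together with age. Each barcode prefix holds a young and an aged pool, so the prefix is crossed with age. The cell titles also hold a code that differs between young and aged cells within each prefix. What this code stands for is not given, and a plate or other batch behind it would go with age. Within each prefix the pos share was higher in the aged pool (63.6% against 41.3%, and 75% against 57.4%). The labels name no day of sorting. Age itself is a candidate explanation that these pools, 2 per age, do not separate from how each pool was sorted.

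In 99 groups of 4 pools, 11 had a pool far from the other 3, where chance gives 1 in 20, or 4.95. In 4 of the 11 the other pools are all at 0, which gives a ratio of 1 whatever the count, and the other 95 groups had 7, where chance gives 4.75. The measure is the gap of that pool to its nearest neighbour over the range of the group. The pan-endothelial score of aged pos pool 1 was 8.36, against 7.74 to 7.84 in the others (0.832). Sdc1 in aged pos pool 2 was at 46.8 CPM, against 115 to 121 (0.917), and Mfsd2a in young pos pool 2 at 160 CPM, against 69.9 to 76.9 (0.922). In neg pools Kdr was at 386 CPM in young pool 1, against 599 to 624 (0.895), Ctnnb1 at 1354 CPM in young pool 2, against 931 to 956 (0.941), Icam1 at 7.04 CPM in young pool 1, against 0 to 0.335 (0.952), and Myl9 at 44.5 CPM in aged pool 1, against 0 to 0.0479 (0.999). Ch25h, Cytl1, Gpm6a and Sdc1 are those 4: they had 1, 38, 1 and 2 reads in young neg pool 2 (0.0479, 1.82, 0.0479 and 0.0957 CPM) and none in another neg pool, so their ratio of 1 says nothing.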

How the results depend on the processing

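Leaving out cells that resemble another type on a list of at least 3 genes, list and per-cell results on further subsets of cells, and lists without Vcam1, were chosen after seeing the data. The differences between gates in Vcam1 share and in the 4 list scores kept their direction and their side of the threshold (the pan-endothelial one, which did not pass, growing from -0.07 to -0.48 at most) when cells were thinned, when the minimum or pseudocount was 10, and with at least 1000 genes per cell. With 3 pools a side or with swaps within pools, their exact tests cannot pass.

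The 40 genes between the gates became 1478 with DESeq2, 0 with the replicate block and 10 without the 69 cells above pan-endothelial on any other list; all 40 kept their sign in each. With limma-trend 35 were called, 22 of them among the 40. The exclusion of the 69 cells rests mainly on Stmn2, for which 61 cells scored high. When a pool was left out, all 40 genes kept their sign. Their median absolute log2 fold change was then 2.40 to 2.66, against 2.53 with all pools. The 40 genes were chosen on these same pools, and 39 of them had the same direction in all 4. That their signs held was thus close to fixed beforehand and adds no support. Leaving out a pool gave 0 to 2 calls. In young pools the 7 genes became 723 with DESeq2, 0 with the replicate block, 12 without a low-count filter, 12 with limma-trend, 0 without those 69 cells and 0 to 0 without a pool. In aged pools the count of 0 became 1222 with DESeq2, 2 without a low-count filter, 5 with limma-trend, 11 with thinned cells, 7 with at least 1000 genes per cell and 0 to 1 without a pool. DESeq2 also gave 570 genes between ages, 392 in pos, 921 in neg and 807 for the interaction, where every other setting gave 0. The 12 lists between the gates became 3 with an estimated correlation, with or without Vcam1 in the lists, and 5 to 10 without a pool. With thinned cells 12 lists passed, 11 of them the same. The Wnt and barrier-inducing list then did not pass, and the mitochondrially encoded list did. The 1 list between ages became 0 with an estimated correlation, again with or without Vcam1, and 0 to 1 without a pool. The block also ended the call of the pan-endothelial list in young pools (10 lists became 9) and added that of the smooth muscle list in aged against young neg pools; it changed no other call.

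The sign turned for 9 values of genes that had not passed. Between the gates, without the 69 cells, the log2 fold changes were -0.0798 for Sox18, 0.0277 for Lef1, -0.0906 for Mfng, -0.21 for Hey1 and -0.31 for Myl9. Lef1 was 0.0208 with limma-trend and ran from -0.32 to 0.0401 (without aged pool 1) when a pool was left out, and Mfng ran from -0.27 (without aged pool 2) to 0.54. Between ages, Hspb1 ran from -0.25 to 0.0080 (without young pool 2). The median log2 fold change of all genes between the gates was 0.08, and 0.18 with limma-trend. Except where fewer pools or cells were used, the cause was not tested. Depth limits genes near 0 most, where single cells carry most reads.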

Other observations

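Of the tests below, those of reads and genes per cell, other cell types, the median pos cell, vessel mix among aged cells and handling were chosen after the result was seen. Within the pos gate, the share of cells with a Vcam1 read was also taken by vessel class and age. In venous-like pos cells it was read in 19 of 28 aged cells (67.9%) and 12 of 36 young cells (33.3%), with pools at 69.2% and 66.7% against 40% and 25%. In arterial-like pos cells it was read in 21 of 24 aged cells (87.5%) and 29 of 41 young cells (70.7%), with pools at 66.7% and 94.4% against 60% and 76.9%. In capillary-like pos cells it was read in 3 of 6 aged cells (50%) and 4 of 10 young cells (40%), with pools at 50% and 50% against 28.6% and 66.7%. These shares by age were not tested.

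The gates differed in vessel segment and adhesion genes. Both gates of a pool hold cells of the same mice, and 8 of the 35 splits of the 8 sums part all 4 pools, too few for a share under 0.05. Of these 8, 1 gave as many genes, the real one (47 in a design with age and split, highest other 0), and 1 as many lists (11, highest other 8). The splits that keep both gates of a pool together in some pools gave 0 genes and 0 to 6 lists. With the pool as a block edgeR called 0 genes (699 at an unadjusted p under 0.05), and DESeq2 without the block called 1478. More reads per cell in the pos gate were argued against, since 36 of the 40 genes were still called with thinned cells. More genes per cell stay open: after thinning, pos cells still had 318 more genes than neg cells, of 405 before. Cells of another type stay open too, since 10 of the 40 genes were still called without the 69 cells above pan-endothelial on any other list. The median absolute log2 fold change of the 40 genes was then 2.14 (median SE 0.35), against 2.53 (median SE 0.31) with all cells, so calls ended with a lower fold and a wider error. Of those cells 61 scored high for Stmn2, which is also an arterial marker, so arterial cells may have been taken out. Leaving out only the 5 cells that resemble another type on longer lists changed too little to decide (40 still called). The mix of vessel segments differed between the gates in a clustering without the called genes. Arterial-like cells were 63 pos and 7 neg, and venous-like cells 46 pos and 1 neg. This mix is a candidate explanation. Within the capillary-like cells of that clustering, the median difference of the called genes was 1.25 on the log2 scale, against 2.51 over all cells. That lies barely under the bound of 0.5 of the whole set beforehand (ratio 0.49968, and 0.329 to 0.505 by pool). Within the class 35 of the 40 genes kept their direction on the mean of pools (36 pos and 127 neg cells). By pool it was 35 in each young pool, and 25 and 27 in aged pools 1 and 2, which had 4 and 8 such pos cells. The 40 genes and their directions were chosen over all cells, these included. That choice favours large differences over all cells, and part of the agreement in direction is built in. The ratio therefore does not divide the difference between the mix and the rest. The class holds 2 clusters, of 13 pos and 85 neg and of 23 pos and 42 neg cells. With the cells of all pools summed by gate, the median difference was 1.33 and 1.38 within these clusters and 1.34 in both together, against 2.37 over all cells, which is over that bound of 0.5 and leaves the share due to the mix uncertain.

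The immediate early and dissociation stress list was higher in aged pools at camera's preset correlation. It did not pass with an estimated correlation (adjusted p = 0.993), nor without young pool 1, aged pool 1 or aged pool 2. For the neg gate, a few cells carrying the list were argued against, in a test set beforehand: the median neg cell was 0.71 higher in aged pools on the log2(CPM + 1) scale. For the pos gate a few cells stay open: the median pos cell was 0.24 higher in aged pools on average, but that of aged pool 2 (3.24) lay below that of young pool 2 (3.28). Another mix of segments was argued against in the neg gate, since capillary-like neg cells were 0.96 higher in aged pools. Handling during dissociation could give the same picture and cannot be told apart from age: the lower aged pos pool lay above the higher young pos pool by 0.0207, and pool and dissociation go together. Age stays open as an untested explanation.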
